A study of Mus musculus with 6 samples.

How the data were processed

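Hippocampal gene expression was measured by RNA sequencing in 6 C57Bl/6 mice aged 4 months, 3 per group. Per the labels' protocols, all mice went through contextual fear conditioning, recall of the memory by re-exposure to the context, and spaced extinction training. One group received the histone deacetylase inhibitor CI-994 at 30 mg/kg every day and the other its vehicle. The hippocampi were frozen 1 h after the last extinction session, and total RNA of the whole hippocampus of one hemisphere was sequenced. The series' design text calls the 3 mice of each group biological replicates. The labels do not give the sex of the mice.

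Reads were processed with TopHat and Cuffdiff on genome build mm9, per the submitters' processing notes. Their versions, the gene annotation, the library normalisation, strand handling and filters are not given in the sources used here. The values come from the authors' table of 475 genes, each with a locus, 1 value per group, a log2 ratio and a p-value. The group values are a normalised expression signal in arbitrary units, per the file headers, and the 3 libraries of a group had been combined by the authors before the values were deposited. The p-value column is the authors' deposited test of CI-994 against vehicle. Its header does not call it adjusted, all of its values lie below 0.05, and 6 values are given as 0. The number of genes the authors tested is not given in the sources used here. Values per mouse were not analysed here, so no replicate error, sequencing depth or test across mice could be computed, and the p-values rest on the authors' treatment of the spread between libraries.

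The deposited log2 column is headed as CI-994 against vehicle. In all 475 genes it equals the log2 of the vehicle value over the CI-994 value, within 0.0001, and in 0 genes does its sign match that header. Directions were therefore taken from the labelled group values, as the log2 ratio of CI-994 over vehicle. If the header of the log2 column is right and the labels of the group values are exchanged, every direction given below turns around.

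Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The following were fixed before the data were examined: the tests, the rule for genes named in the text, 38 gene lists (16 of cell type or region markers and 22 of pathways) and the alternative settings, except those said to have been chosen later. A table of per-sample counts or FPKM would have been tested with a model across libraries. As the table held changed genes only, membership of the table decided which genes were called changed, as the design provided for that case. The share of genes higher in CI-994 was set against 50% with a two-sided exact binomial test and an exact Clopper-Pearson 95% interval. For each gene list with at least 3 members in the table, higher and lower members were compared with the genes outside the list by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists tested. Since unchanged genes were not in the table, enrichment of a list among changed genes had no background and was not tested. The median log2(value + 1) in vehicle and the median log10 span of the locus were compared between higher and lower genes with two-sided permutation tests of 100000 resamples, which give a smallest p of 1e-05. The 4 such comparisons of level or length were adjusted together. Genes are not independent replicates, so these tests describe the table and not the animals. For a count adjusted over a list alone, the deposited p-values of the list were adjusted with members outside the table set to 1.

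The named genes were the 12 largest increases and the 12 largest decreases with at least 1 unit in both groups, up to 3 higher and 3 lower members of each list, Hdac1, Hdac2, Hdac3, Fos, Arc, Egr1, Npas4 and Bdnf where present, and the 3 genes of each direction with the highest vehicle value. Other genes named were chosen after their values were seen, and this is said where they appear, except for Csrnp1, Ctxn3 and Ttr, which also lie outside the rule. Gene type and summed exon length were taken by symbol from a newer mouse annotation (GENCODE M21), which matched 474 of the 475 symbols (99.8%), 30 of them through an older name. That annotation is on another build, so its coordinates were not used. Coordinates are given as in the authors' table (mm9).

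The list test was tested on simulated tables of 475 genes. A choroid plexus list with 90% of its members higher was found in 100 of 100 tables, while a dentate granule cell list with 10% of its members higher was found in only 27 of 100. In 100 tables with no list of its own direction, 0 gave a call. Each simulated gene took its direction independently, so these rates do not cover lists whose genes move together. As only 27 of 100 dentate lists were found, a list that missed the threshold is not shown to lack a direction. A level shift of 0.8 log2 units was found in 50 of 50 tables and with no shift 0 of 50 gave a call. Alternatives covered the p-value and fold thresholds, a least level of 1 unit, pseudocounts of 1 and 0.1, the comparison set of the lists, the statistic and the measure of length.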

Results

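The study asked how an HDAC inhibitor given around the extinction of a fear memory alters gene expression in the hippocampus. CI-994 is a benzamide inhibitor of class I histone deacetylases, the enzymes that remove acetyl groups from histone tails. The table analysed here held 475 genes that the authors listed as changed between 3 CI-994 and 3 vehicle mice, with 1 value per gene and group in arbitrary units. No error or depth came with these values, so the group values below stand without a spread, and the p-values of single genes are those of the authors' deposited table. Directions follow the labelled group values, and they would all turn around if those labels were exchanged, as the header of the authors' log2 column would have it.

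Immediate early genes, the neuronal genes transcribed within minutes of activity, included some of the clearest increases. Npas4, an activity-dependent transcription factor, was at 4.43 units in CI-994 and 0.887 in vehicle (4.99-fold higher, log2 ratio 2.32). Fos, a subunit of the AP-1 transcription factor, was at 12.3 against 4.03 units (3.05-fold higher), and Arc, which acts in AMPA receptor endocytosis, at 67.4 against 37.4 units (1.80-fold higher). In the authors' deposited table their p-values were 1.18e-08, 1.97e-08 and 2.37e-08. Dusp1 (log2 ratio 0.93), Gadd45b (0.84) and Csrnp1 (0.67) were also higher, while Ptgs2 (-0.55), Jun (-0.48) and Per1 (-0.40) were lower. The group was thus divided, with 6 members higher, 3 lower and 52 of the 61 not in the table, among them Egr1. A difference in direction from the other genes was not detected (Fisher's exact test, adjusted p = 0.413). Adjusted over the list alone, 6 members passed, 5 higher and 1 lower. In mm9 coordinates, Npas4 lies on chromosome 19 from 4984354 to 4989971, Fos on chromosome 12 from 86814850 to 86818219 and Arc on chromosome 15 from 74499512 to 74503000.

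Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, made up most of the largest increases. Of 30 markers, 27 were in the table and all 27 were higher in CI-994, with a median log2 ratio of 2.54. Tmem72 (log2 ratio 4.00), the bicarbonate transporter Slc4a5 (3.99) and Steap1 (3.84) led the list. Kcnj13, a potassium channel of this epithelium, was at 22.1 against 1.98 units (11.2-fold), the folate receptor Folr1 at 11.3 against 1.27 units (8.90-fold) and Enpp2, which makes lysophosphatidic acid, at 377.0 against 75.3 units (5.00-fold). Clic6 (log2 ratio 2.76), Sostdc1 (2.73), Wfdc2 (2.26), the peptidase Ace (1.99) and the sulfatase Sulf1 (1.98) were among the 12 largest increases that reached 1 unit in both groups. Rdh5 (2.36), 1500015O10Rik (2.80), Ccdc135 (2.05) and Slc2a12 (1.82), which were not on the list, also belonged to those 12. The direction of the list differed from that of the other genes (Fisher's exact test, p = 2.1e-11, adjusted p = 4.21e-10), and 27 members passed when adjusted over the list alone. Choroid markers supplied 18 of the 30 largest increases, and 12 of the 27 had a vehicle value under 1 unit. Ttr, the most abundant choroid plexus transcript, was not among the genes in the table.

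Markers of dentate granule cells, the principal neurons of the dentate gyrus, moved the other way. Of 27 markers, 18 were in the table and all 18 were lower in CI-994, with a median log2 ratio of -0.73. C1ql2, a synaptic organiser of mossy fibres, had the largest fall of any gene with at least 1 unit in both groups, from 52.5 units in vehicle to 10.5 in CI-994 (log2 ratio -2.32). The opioid peptide precursors Pdyn (-1.51) and Penk (-1.46) followed. The direction of the list differed from the rest (Fisher's exact test, adjusted p = 0.000822), and 17 members passed when adjusted over the list alone. Markers of pyramidal cells in the table were lower as well, with Wfs1 (-0.74), Htr1a (-0.41) and Man1a (-0.32) of CA1 and Cacng5 (-1.44), Iyd (-0.96) and Bok (-0.67) among those of CA3 and CA2. These were 3 of 17 and 4 of 23 markers, all lower, and neither list passed (adjusted p = 0.413 for both, Fisher's exact test). With so few members the test could not pass even when all were lower (Fisher's exact p before adjustment 0.268 and 0.143). It therefore does not set these lists apart from the dentate list. Adjusted over each list alone, 1 CA1 marker and 3 CA3 and CA2 markers passed. The choroid plexus increase described above accompanied this fall in the same samples.

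The third list with a direction of its own was extracellular matrix and perineuronal nets, of which 6 of 72 genes were in the table and all 6 were higher (Fisher's exact test, adjusted p = 0.0345). Col8a1 (log2 ratio 2.54) and Col8a2 (2.50), collagens that were also on the choroid plexus list, and Col9a3 (1.36) led it, and 3 members passed when adjusted over the list alone. Its adjusted p was 0.202 when the choroid plexus markers were left out, a setting chosen after seeing the data, 0.214 for genes with p up to 0.01 and 0.36 for genes with at least 1 unit in both groups.

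**Figure D1:**
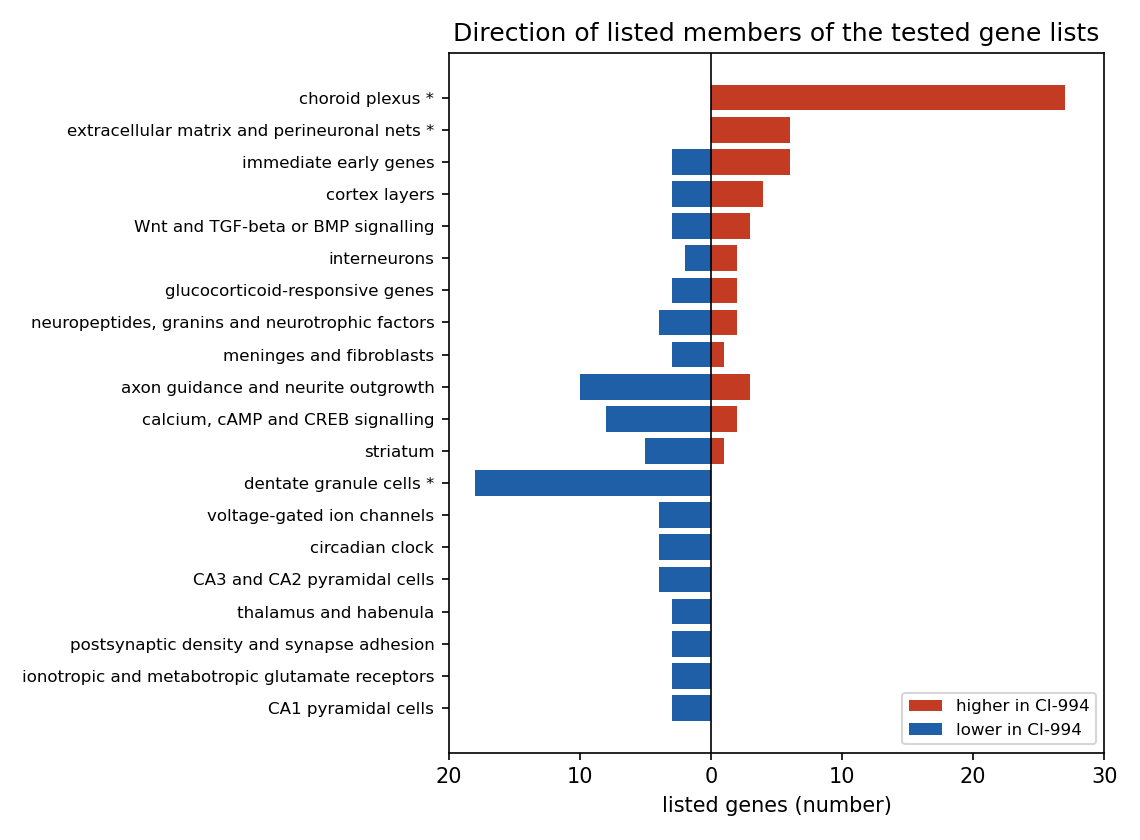
Number of genes in the authors' table that were higher (red, to the right) or lower (blue, to the left) in CI-994 than in vehicle, for the 20 gene lists with at least 3 members in the table. Lists with an adjusted p under 0.05 by Fisher's exact test carry an asterisk: choroid plexus with 27 higher, extracellular matrix with 6 higher and dentate granule cells with 18 lower.

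Few genes of synaptic transmission were in the table, and none of these lists passed. The 3 of 33 glutamate receptor genes in the table were lower, led by the presynaptic receptor Grm2 (log2 ratio -0.80), then Grik3 (-0.44) and Cacng8 (-0.34). The same held for 3 of 51 postsynaptic and adhesion genes, Lrrtm4 (-0.91), Ephb2 (-0.53) and Nrxn3 (-0.33), for 4 of 78 voltage-gated channel genes such as Kcnip4 (-0.48), Kcns2 (-0.45) and Kcnd2 (-0.42), and for 2 of 27 GABA and glycine genes, the receptor subunits Gabrd (-0.76) and Gabra5 (-0.33). The 2 of 49 presynaptic genes, both lower, were Doc2b (-0.88), a calcium sensor, and Slc17a6 (-0.72), a vesicular glutamate transporter. Of 75 axon guidance genes 13 were in the table, and 10 were lower, among them Sema5a (-1.03), Plxnd1 (-0.99) and Sema5b (-0.83), while Robo3 (1.09), Gap43 (0.37) and Plxnc1 (0.33) were higher. Of 64 calcium and cAMP signalling genes 10 were in the table, and 8 were lower, such as Prkcd (-0.82), Pde7b (-0.76) and Pde1b (-0.49), against Ryr1 (1.00) and Ppp1r1b (0.46), which were higher. The 4 of 21 circadian clock genes in the table, including Hlf (-0.49), Bhlhe41 (-0.46) and Bhlhe40 (-0.42), were all lower. By Fisher's exact test the adjusted p was 0.413 for each of these lists that had at least 3 members in the table. The glutamate receptor, postsynaptic, channel and circadian lists were wholly lower, yet too small to pass this test. Their result does not show that they lacked a direction. Adjusted over the list alone, 3 calcium and cAMP genes passed, 2 axon guidance genes, 1 gene each of the glutamate receptor, postsynaptic and circadian lists, and 0 channel genes.

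Neuropeptide and growth factor genes were divided. The growth factor Igf2 (log2 ratio 1.38) and the interneuron peptide Vip (0.69) were higher, and 4 genes were lower, with Adcyap1 (-1.34) beside Pdyn and Penk (adjusted p = 1, Fisher's exact test). In the Wnt and BMP list 3 members were higher, Sfrp1 (0.93), Bmp6 (0.80) and Inhbb (0.74), and 3 were lower, the BMP antagonist Grem1 (-2.02), Wnt9a (-0.79) and Smad3 (-0.60), with an adjusted p of 0.822 by the same test. Glucocorticoid-responsive genes comprised Plin4 (1.92) and Dusp1, which were higher, and Bcl6 (-0.48), Per1 and Fkbp5 (-0.32), which were lower (Fisher's exact test, adjusted p = 1). Adjusted over each list alone, 4 neuropeptide and growth factor genes, 1 Wnt and BMP gene and 3 glucocorticoid-responsive genes passed. Genes of lists with fewer than 3 members in the table, which were not tested, included the cyclin-dependent kinase inhibitor Cdkn1c (1.01), the interferon-induced Bst2 (1.31), the MHC class II chain Cd74 (1.29), the methyltransferase Setd2 (0.35) and the linker histone H1fx (-0.37). No member of the lists of histone deacetylases and sirtuins, histone acetyltransferases and bromodomain proteins, heat shock and unfolded protein response, cholesterol synthesis or mitochondrial respiration was in the table. Hdac1, Hdac2, Hdac3 and Bdnf were accordingly not among its genes.

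Markers of other cells and regions were sparse. Microglial and macrophage markers were not in the table, and single genes stood for astrocytes (Aqp4, -0.34), endothelium (Vwf, -0.51), the oligodendrocyte lineage (Hapln2, 0.72), ependyma (1700009P17Rik, 1.04) and blood (Beta-s, a beta globin, 0.60). The Cajal-Retzius markers Calb2 (-0.52) and Reln (-0.39) were lower. Among meningeal markers Aldh1a2 (-1.15), Fmod (-1.14) and Ptgds (-0.53) were lower and Igf2 was higher (Fisher's exact test, adjusted p = 0.804). Of 7 cortical layer markers 4 were higher, Sulf1, which is also a choroid plexus marker, Scube1 (0.83), Tbr1 (0.35) and Nefm, and 3 lower, 6330527O06Rik (-0.66), Rprm (-0.65) and Lmo3 (-0.32), with an adjusted p of 0.613 by the same test and 3 of each direction without Sulf1. Interneuron markers were even, with Htr2c (1.12) and Vip higher and Calb2 and Reln lower (Fisher's exact test, adjusted p = 1). Striatal markers were 1 higher and 5 lower (Fisher's exact test, adjusted p = 0.583), and the 3 thalamic and habenular ones were lower (adjusted p = 0.413).

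In all, 199 of the 475 genes were higher and 276 were lower in CI-994. The share of higher genes was 41.9% (exact 95% interval 37.4 to 46.5%), below 50% (two-sided exact binomial test, p = 0.000476). Among the genes listed the increases were larger, with a median of 1.76-fold against 1.42-fold for the decreases. At least 2-fold higher were 80 genes, against 34 at least 2-fold lower. Choroid plexus markers were 18 of the 30 largest increases, and the higher genes had a lower vehicle level, as given below. The median absolute log2 ratio was 0.62, and ratios ran from -8.01 for Uty to 4.32 for Cox8b, a muscle-type cytochrome c oxidase subunit on none of the lists, both named after their values were seen. Among the remaining large decreases with at least 1 unit in both groups were A230065H16Rik (-1.88), Clec3b (-1.84), Aard (-1.40), Lect1 (-1.39), Nsun3 (-1.36), Krt9 (-1.34) and Net1 (-1.30). The share depended on the threshold: it was 47.5% at p up to 0.01, 56.1% at p up to 0.001 and 70.2% among genes with an absolute log2 ratio of at least 1. Between 0.02 and 0.05 lay 181 of the p-values in the authors' deposited table, and a flat distribution of that density would place 302 genes below 0.05, a calculation chosen after seeing the data. That number is 63.5% of the genes listed, with 57.8% for the higher and 67.6% for the lower genes. If genes without a difference gave that density, up to such a share of the table could be genes of this kind.

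**Figure D2:**
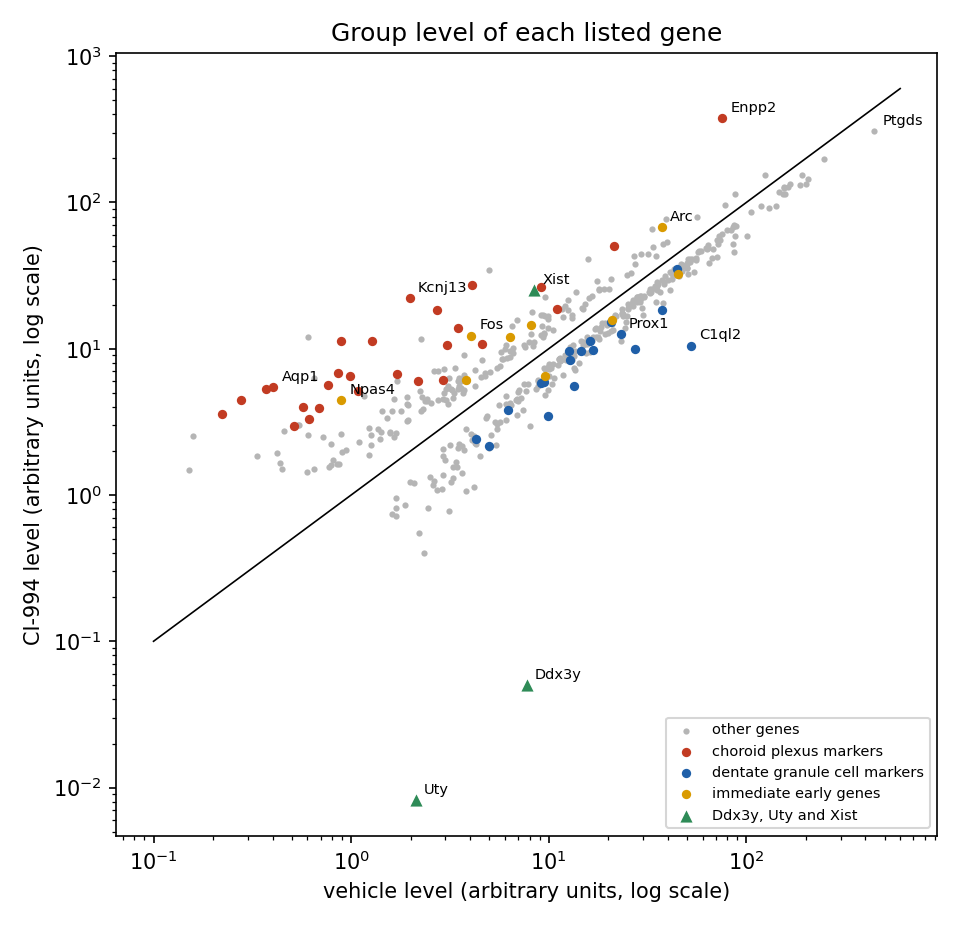
Expression level of each of the 475 genes in CI-994 (vertical axis) against vehicle (horizontal axis), both in arbitrary units on log scales, with 1 point per gene and the line of equal levels. Choroid plexus markers (red) lie above the line, dentate granule cell markers (blue) below it, and the Y-linked genes Ddx3y and Uty far below it at 0.0503 and 0.00821 units in CI-994.

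Among the genes listed, those higher in CI-994 had lower median levels than those that were lower. Unchanged genes were not in the table for comparison. The median vehicle level of the higher genes was 3.53 units, against 18.3 units for the lower genes, a difference of -2.09 in median log2(value + 1) (permutation test, p = 1e-05, the smallest it can give, adjusted p = 4e-05). A vehicle value enters both the level and the direction, but the CI-994 level, set beside it after seeing the data, was also lower in the higher genes, at 6.86 against 12.4 units (difference -0.77, permutation p = 2e-05, adjusted p = 4e-05). The most abundant genes that were higher were Sparc (log2 ratio 0.32), Gap43 and the neurofilament gene Nefm (0.31). The most abundant that were lower were Ptgds, which makes prostaglandin D, at 307 against 443 units, Camk2n1 (-0.32), an inhibitor of CaM kinase II, and Ncald (-0.49). Higher genes also spanned less of the genome, with a median locus of 23.6 kb against 48.1 kb (difference -0.31 in log10, permutation p = 0.00048, adjusted p = 0.00064). Their summed exon length did not pass, at 4.84 against 5.30 kb (permutation p = 0.299).

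The Y-linked genes Ddx3y and Uty were at 7.73 and 2.12 units in vehicle and near 0 in CI-994, with log2 ratios of -7.27 and -8.01. Xist, the RNA that coats the inactive X chromosome, was at 25.3 units in CI-994 and 8.46 in vehicle. Of the 16 X-linked genes in the table, Xist included, 11 were higher and 5 lower. These genes were chosen after their values were seen.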

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

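Settings that left out choroid plexus or other markers, assumed a number of tested genes, replaced the vehicle level by the CI-994 level, or read the sign of the log2 column by its header were chosen after seeing the data. The 475 genes became 236 at p up to 0.01, 123 at 0.001, and 294 and 114 at an absolute log2 ratio of at least 0.5 and 1, because each admits fewer genes. Benjamini-Hochberg adjustment over an assumed 10000, 15000 or 20000 tested genes left 110, 100 or 90 genes, of which 25, 25 and 24 were choroid markers and 8, 8 and 7 dentate markers, against 27 and 18 in the whole table. The share of higher genes was 47.5% at p up to 0.01 (exact binomial p = 0.474), 56.1% at 0.001 (p = 0.207), 53.1% at a log2 ratio of 0.5 (p = 0.321) and 70.2% at 1 (p = 1.96e-05). Without choroid markers it was 38.4%, and without dentate markers, Ddx3y, Uty and Xist as well 40.0% (exact binomial p = 4.55e-05). The extracellular matrix list stayed at 100% higher but lost its call at p up to 0.01 (4 genes), with at least 1 unit in both groups (3 genes) and without choroid markers (4 genes), with fewer members in each test. In that last setting 1 list passed in place of 3, since the choroid list itself was no longer tested and the matrix list lost its call. The exon length difference in log10 was -0.039 (permutation p = 0.299), and the cause was not tested. The choroid and dentate lists kept direction and call under each setting fixed beforehand, as did the vehicle level difference. Of 53 values of single lists under these settings 48 kept direction and side. The others were the matrix list and lists that never passed: Wnt and BMP at 33.3% for p up to 0.01, and glucocorticoid-responsive genes at 66.7% for p up to 0.01, for which the cause was not tested. With choroid, meningeal and blood markers out of the comparison the latter stayed at 40.0%, but the comparison genes then had a lower share than the list, and so they had in the later setting without choroid markers. Read by the header of the log2 column, all 475 directions turn by construction: the share becomes 58.1%, the choroid and matrix lists 0% and the dentate, CA1, CA3 and CA2, thalamic, circadian, glutamate receptor, postsynaptic and channel lists 100% higher, with striatum at 83.3%, calcium at 80%, axon guidance 76.9%, meninges 75%, neuropeptides 66.7%, glucocorticoid 60%, interneurons and Wnt 50%, cortex 42.9% and immediate early genes 33.3%, the level difference 0.77 and the length difference 0.31. A pseudocount of 1 or 0.1 turned 0 of the 106 named genes, and 39 of them had a p above 0.01. No paired analysis was possible because the authors' values are 1 per group, and for the same reason leaving out a mouse, a DESeq2 fit and a per-sample pseudocount were not run. Depth is unknown, so what it limits could not be assessed.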

Other observations

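All tests of explanations in this part were chosen only after the result was seen, and so were the gene groups of the next paragraph.

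The 10 long noncoding RNAs in the table were all higher in CI-994, 8 of them off the X chromosome. Of the protein-coding genes 188 were higher and 275 lower (Fisher's exact test, p = 0.000144). As the group was found from its values, this p carries no weight. Besides the X-linked Xist and 6720401G13Rik they included the paraspeckle RNA Neat1 (log2 ratio 1.24), Malat1 of nuclear speckles (0.73), Meg3 (0.98) and Rian (0.56) of the same imprinted locus, Miat (0.69) and Sox2ot (1.41). Other imprinted genes went both ways, with Igf2 and Cdkn1c higher and Ndn lower at 91.3 against 130 units (-0.52). The neuropeptide Y receptor genes Npy1r (-0.59), Npy2r (-0.81) and Npy5r (-0.78) were all lower, and Npy1r was also on the dentate list.

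The choroid plexus increase may reflect unequal amounts of that tissue in the dissected hippocampi, since the plexus adheres to the hippocampus. This needs nearly all markers to rise together, and 27 of 30 were listed as higher and 0 as lower, with Enpp2 at 377.0 units, although Ttr was not in the table. That count is also the one that prompted the explanation. A response shared by all markers would give it too, so it does not separate the explanations. A response of choroid plexus cells to the drug stays open. The 12 markers under 1 unit in vehicle had an SD of 0.62 in log2 ratio, about the error of 0.57 that their p-values in the authors' deposited table imply, which neither demands a single factor nor excludes one. With 1 value per group the tissue of each mouse could not be compared.

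For the dentate decrease 3 explanations were weighed: dilution by choroid plexus RNA, a smaller share of dentate gyrus, and a change within granule cells. Dilution lowers them by a single factor. The 18 markers had an SD of 0.50 in log2 ratio, with C1ql2, whose p is given as 0, included. The error that the authors' deposited table implies for the 17 with a p above 0 was 0.24 (Cochran's Q 40.9 over these 17, p = 0.000578). Only 9 of the 17 were precise enough to be listed under a single factor whatever their error, short of the 10 set for rejecting one. The table holds only genes with a p below 0.05, which can widen such a spread. Cochran's Q therefore cannot decide on a single factor. A smaller dentate share predicts that pyramidal cell markers do not fall, and 7 of the 40 were listed as lower and 0 as higher. Dilution would lower other neuronal genes too, but only 4 of 78 voltage-gated channel genes and 3 of 51 postsynaptic and adhesion genes were listed, all lower. These counts argue against dilution as the only cause of the dentate decrease, although the ratios of genes outside the table are unknown. A part played by dilution is not excluded. Most of the 40 pyramidal markers are not in the table, so a smaller dentate share and a change within granule cells cannot be told apart.

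The levels of Ddx3y, Uty and Xist are in line with different numbers of male and female mice in the groups, which the labels do not describe. The vehicle level of Xist was 33.5% of its CI-994 level, close to what 1 female among 3 vehicle mice and CI-994 mice that were all female would give, and both Y-linked genes were at most 0.65% of their vehicle level in CI-994. A response to the drug would need falls far beyond that of any gene off the Y chromosome, of which the largest was -2.54 for Ctxn3. The log2 ratios of -7.27 for Ddx3y and -8.01 for Uty argue against such a response for these genes, although 1 value per group cannot settle it. Sex may then differ between the groups beside the treatment, and with these values it cannot be separated from the treatment in any comparison given here. Its part in the other changes was not tested.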
